A study of Homo sapiens with 2 samples.

How the data were processed

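Single-cell RNA sequencing was carried out on 2 samples of A375, a human melanoma cell line. The parental sample was untreated. The CTL persister sample held A375 cells that were alive after 15 days of coculture with cytotoxic T lymphocytes (CTLs) directed at NY-ESO-1, a cancer-testis antigen, in medium with 7.5 ng/mL interleukin 2, and fresh CTLs were added every 3 days. The labels do not say whether the parental cells received interleukin 2. Cells were detached with trypsin, and libraries were made with the 10x Chromium 3' v3 kit, per the labels' protocols. Each group has 1 library, so there is no replicate check of any difference.

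The deposited values are UMI counts per gene and barcode, not normalized, per the file headers and the whole-number values. A UMI count is the number of distinct molecules seen. Cell Ranger 3.1.0 and the GRCh38 build are named in the submitters' processing notes. The annotation release used for counting is not given in the sources used here. Counts of near-identical genes depend on how reads that fit several genes were treated. The values for CTAG1A and CTAG1B, HSPA1A and HSPA1B, the MAGEA and GAGE families and the HLA genes are therefore uncertain, as are genes whose annotated ranges overlap, such as HLA-B and HLA-C.

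Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrially encoded UMIs. This kept 10630 of 10751 parental and 6767 of 7144 persister barcodes. More than 20% mitochondrially encoded UMIs was found in 32 parental and 160 persister barcodes. Kept barcodes of both libraries were clustered together without batch integration in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). A cluster was called T-cell-like from at least 2 T cell or cytotoxic effector genes among its leading genes and at least 3 detected T cell markers, and melanoma-like from melanoma markers. Clusters of low depth without T cell or melanoma markers among their leading genes stayed unnamed (176 parental and 381 persister barcodes) and were kept in the comparison. Melanoma-like clusters also had 0 melanoma markers among their leading genes, so depth set the unnamed clusters apart. The unnamed clusters 7, 10 and 5 had 20, 19 and 9 melanoma markers detected. Among these, cluster 10 with 377 persister barcodes, had the cytotoxic effector gene IFNG among its leading genes. Scrublet called 0 doublets in either library, which was not taken to mean that doublets were absent, and no barcode was removed as a doublet. Nearly every cluster was made of 1 library, so no cluster was matched to a cluster of the other library. Shares and values of single clusters are given below as descriptions.

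For expression, the UMIs of all kept barcodes outside the T-cell-like cluster were summed per library, giving 88110998 UMIs from 10630 parental cells and 79953631 UMIs from 6632 persister cells. Values are counts per 1000000 UMIs (CPM). Genes with at least 5 CPM in either library were called measured. Log2 folds are on the log2(CPM + 1) scale, which understates the difference of low genes, while plain folds are ratios of CPM. No test between groups is possible with 1 library each, and none was run. Intervals are 95% exact Poisson intervals for sums and exact Clopper-Pearson intervals for shares of cells. These intervals cover counting error only, and so does the floor for a count of 0, taken as 3 UMIs (0.0341 CPM parental, 0.0375 CPM persister).

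Before the data were examined, 35 gene lists, the marker genes, the comparisons and the alternative settings were fixed. For each list with at least 5 measured members, the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a p-value. Named genes were chosen by a rule fixed at the same time. It took the 15 genes with the largest log2 fold in each direction at 20 CPM or more, then up to 3 members of each list with the largest absolute log2 fold at 5 CPM or more. It also took a fixed set of genes, some of which are not reported here: the NY-ESO-1 genes, B2M, HLA-B, HLA-C, CD274, IRF1, MKI67, CDKN1A, MITF, SOX10, AXL, NGFR, GPX4 and SERPINB9. Mitochondrial, ribosomal and clone-named genes were not taken by size alone. T cell receptor and immunoglobulin segments and sex-linked genes that could describe a CTL donor (652 gene IDs) were left out of all gene tables.

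For values per cell, each cell was thinned at random to 5000 UMIs, which left out 1536 parental and 706 persister cells of lower depth. Cell cycle phases were scored in scanpy from the S phase and the G2 and M phase lists. RNA of T cells in the persister sum was estimated from T cell markers, with the T-cell-like cluster as the profile. Chromosome positions are from GENCODE 29 on GRCh38, matched by gene ID for 33456 of 33538 IDs. The steps were tested on simulated sums for the persister against parental comparison, with 200 of 9372 measured genes altered. All 58, 44, 50 and 48 genes given log2 folds of -2, -1.3, 1.3 and 2 were recovered at 2-fold, and 0 of the 9172 unaltered genes were called. Both simulated sums were drawn from the parental profile with Poisson counting noise only. The check therefore covers the calculation and not the rate of false calls between real libraries.

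Alternatives covered the cell filter, T cell RNA, scaling (TMM from edgeR 4.0.16, mean of per-cell CPM, totals without mitochondrial and ribosomal genes), thinning, G1 cells alone, the CPM minimum, the pseudocount, the fold threshold and the clustering resolution. Restriction to melanoma-like clusters, removal of the 8% of cells with the highest doublet scores, and the matrix list sum without TIMP1 were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.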

Results

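The study compared untreated A375 melanoma cells with A375 cells that survived 15 days of coculture with NY-ESO-1 CTLs. The question, from its title and design, was what distinguishes tumour cells that still carry the antigen and persist under direct T cell attack. The parental library held 88214007 UMIs in 10751 barcodes, and its kept barcodes had a median of 7590 UMIs and 2654.5 genes. The persister library held 80802724 UMIs in 7144 barcodes, and its compared cells had a median of 11287 UMIs and 3167 genes. Mitochondrially encoded UMIs made up a median of 5.92% of a parental cell and 7.53% of a compared persister cell. There was 1 library per group, so every difference below describes these 2 libraries, has no replicate check and is given by its size.

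T-cell-like cells were present in the persister library. A T-cell-like cluster, led by GZMB, CCL4, CCL3, CD52 and GZMA, held 135 of 6767 kept persister barcodes, or 1.99% (95% exact interval 1.68 to 2.36%). It held 0 of 10630 parental barcodes, which allows a share of up to 0.0347%. The persister share depended on the setting: it was 0.0976% with a stricter cell filter, and 4.62% when barcodes with 2 or more T cell markers were counted, a rule that gave 0.442% in the parental library. After these barcodes were set aside, the T cell markers summed to 12.1 CPM in parental and 27.0 CPM in persister cells, against 8220 CPM in the T-cell-like cluster. From these, T cell RNA was estimated at 0.182% of the persister sum.

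Interferon and antigen presentation genes were far higher in the persister library. All 26 measured members of the interferon-gamma response list were at least 2-fold higher, with a median log2 fold of 3.41, also when the 2 members with 0 parental UMIs were set to their bound. The list summed to 268.3 CPM in parental and 5199 CPM in persister cells, a 19.4-fold difference. IRF1, a transcription factor of the interferon-gamma response (chromosome 5, 132481609 to 132490798, minus strand), was 17.0 CPM (16.1 to 17.9) in parental and 945.4 CPM (938.7 to 952.2) in persister cells. GBP1, a guanylate-binding protein, was 65.9-fold higher, at 2.42 against 159.3 CPM. CXCL10, a chemokine that attracts T cells, had 1 UMI in parental and 5682 UMIs in persister cells, a ratio of 6262 with a counting interval of 1123 to 247400. Of the 36 measured type I interferon response genes, 31 were at least 2-fold higher and 0 lower, with a median log2 fold of 2.86. Examples are XAF1 (0.216 against 147 CPM), IFI27 (0.182 against 62.5 CPM) and BST2 (3.18 against 205 CPM). Among 16 interferon receptor and signalling genes, 8 were at least 2-fold higher and 0 lower, with a median log2 fold of 0.89; STAT2 was 10.0-fold higher. In cells called G1, of which the parental library had only 405, the log2 fold was 4.87 in place of 5.55 for GBP1, 4.76 in place of 5.62 for BST2, 2.22 in place of 3.09 for STAT2 and 6.34 in place of 5.75 for IFI27.

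MHC class I presentation genes, which display peptides to CTLs, were at least 2-fold higher in 18 of 21 cases and lower in 1, with a median log2 fold of 2.42. B2M, the light chain of MHC class I (chromosome 15, 44711487 to 44718877, plus strand), was 684.6 CPM (679.2 to 690.1) in parental and 6978 CPM (6960 to 6997) in persister cells, 10.2-fold higher. HLA-B was 110.6 against 3296 CPM and HLA-C 66.8 against 612.7 CPM. TAP1, a peptide transporter, was 20.7-fold higher. In the MHC class II list, 13 of 14 measured genes were at least 2-fold higher and 0 lower, with a median log2 fold of 2.25. Its members included the protease CTSS, at 0.499 against 258.4 CPM, HLA-DQA1, at 5.35 against 139 CPM, and HLA-DOA, at 0.817 against 19.6 CPM. The medians of these 4 lists, interferon-gamma, type I, MHC class I and MHC class II, lay above all 10000 matched random lists (percentile 100). Lists with smaller medians also reached percentile 100, such as MAPK output (0.86) and AP-1 and dissociation stress (0.78). This percentile alone does not set the 4 lists apart. T cell RNA was estimated to supply 0.112% of the HLA-B and 0.181% of the B2M signal in persister cells.

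**Figure D1:**
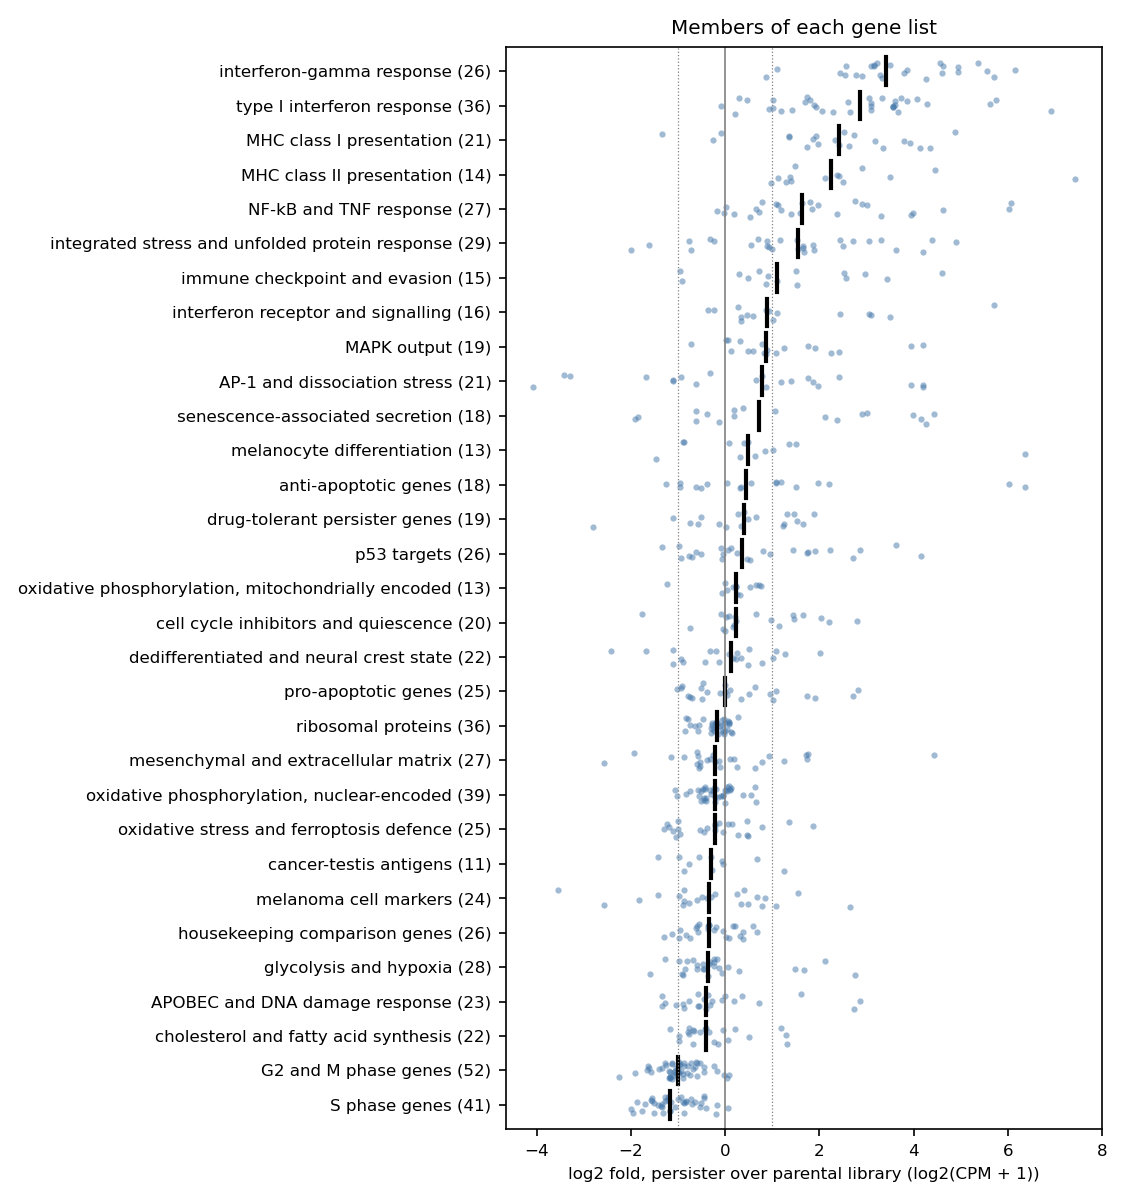
Log2 fold (persister over parental library, log2(CPM + 1) scale) of each measured member of the gene lists. Points are genes, black bars are list medians, the number of genes is in brackets and dotted lines mark 2-fold. The interferon-gamma list has a median of 3.41 and the S phase list a median of -1.18.

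Summed over each list, the interferon-gamma and MHC class I differences were present in nearly every persister cell with at least 5000 UMIs. Single members such as CXCL10 were seen in far fewer cells. At 5000 UMIs per cell, parental cells had a median of 1 UMI from the interferon-gamma list and persister cells a median of 25. Of 5926 persister cells, 99.9% lay above the parental 95th percentile of 4 UMIs. For the type I interferon list the medians were 3 and 15 UMIs, with 90.1% of persister cells above the parental 95th percentile, and for the MHC class I list 13 and 80 UMIs, with 99.97%. Without thinning, over all 6632 compared persister cells, the shares were 98.8% for the interferon-gamma list and 93.7% for the MHC class I list. No parental cell of 9094 reached the persister median for the interferon-gamma or the MHC class I list (0 in each case, exact upper limit 0.0406%), and 4 did for the type I list (0.0440%). At matched depth, IRF1 was seen in 7.97% of parental cells (7.42 to 8.55%) and 96.7% of persister cells (96.3 to 97.2%). Without thinning these were 12.6% and 97.8%, and 46.7% of T-cell-like barcodes, whose median depth was 2834 UMIs, had a UMI.

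**Figure D2:**
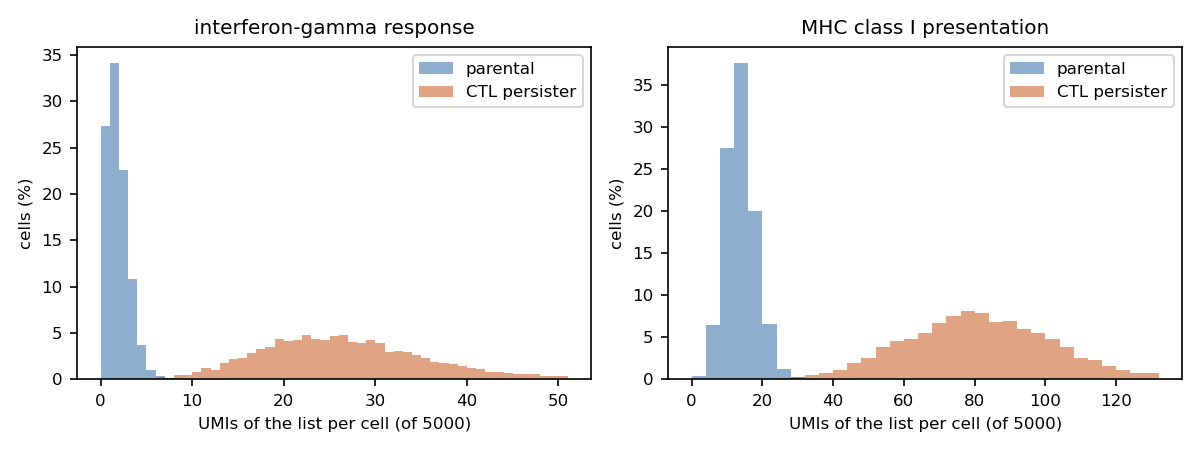
UMIs per cell from the interferon-gamma response list (left) and the MHC class I presentation list (right) in cells thinned to 5000 UMIs; the vertical axis is the percentage of cells of each library. Persister medians are 25 and 80 UMIs against parental medians of 1 and 13.

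Genes that dampen T cell attack differed as well. In the checkpoint and evasion list, 8 of 15 measured genes were at least 2-fold higher and 2 lower, with a median log2 fold of 1.10. CD274, which encodes PD-L1, was 1.79 CPM (1.52 to 2.10) in parental and 20.9 CPM (19.9 to 22.0) in persister cells. At matched depth 0.781% of parental and 9.52% of persister cells had a CD274 UMI. Unthinned, these were 1.44% and 19.3%, against 2.96% of T-cell-like barcodes. IDO1, a tryptophan-degrading enzyme, had 0 UMIs in parental and 23.4 CPM in persister cells. It was 688 times the floor of 3 UMIs, and at least 559-fold higher by the lower limit of the counting interval. At matched depth only 10.6% of persister cells had an IDO1 UMI. TNFRSF14 was 17.2-fold higher. In cells called G1 the log2 fold was 2.37 in place of 2.97 for CD274 and 2.71 in place of 3.44 for TNFRSF14. SERPINB9, an inhibitor of granzyme B, had 0 UMIs in parental and 13 UMIs in persister cells, 59.9% of which could be supplied by the estimated T cell RNA.

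Few UMIs were assigned to the NY-ESO-1 genes targeted by the CTLs in either library. Counts of CTAG1A and CTAG1B depend on how reads that fit both copies were treated. They therefore do not settle how much of the antigen RNA was present. CTAG1A had 48 UMIs in parental cells (0.545 CPM, 0.402 to 0.722) and 30 UMIs in persister cells (0.375 CPM, 0.253 to 0.536), and the intervals overlap. CTAG1B, a near-identical copy, had 13 and 6 UMIs, a ratio of 0.509 with a counting interval of 0.159 to 1.43. CTAG2 was 2.88 CPM in parental and 0.775 CPM in persister cells, 3.72-fold lower. In the cancer-testis antigen list, 1 of 11 measured genes was at least 2-fold higher and 2 lower, with a median log2 fold of -0.30 (percentile 21.5). MAGEA3 was 2.75-fold lower and MAGEA12 2.00-fold lower, while GAGE1 was 2.44-fold higher.

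Over the whole transcriptome, 9938 genes were measured. Of these 1003 were at least 2-fold higher and 1065 at least 2-fold lower in the persister library, so 48.5% of such genes were higher. With TMM scaling the counts were 1147 and 810, or 58.6% higher. The median log2 fold of all measured genes was -0.15, and -0.03 with TMM, so list medians near these values stand no further from 0 than genes at large.

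NF-kB genes were also higher, and genes of cell survival and death were mixed. In the NF-kB and TNF list, 19 of 27 measured genes were at least 2-fold higher and 0 lower (median log2 fold 1.64, percentile 100). BIRC3, an inhibitor of apoptosis, was 0.863 CPM in parental and 121 CPM in persister cells. IL32, a cytokine, was 1.06 against 137 CPM, and ICAM1, an adhesion molecule that T cells bind, was 4.02 against 122 CPM. In cells called G1 the log2 fold was 4.88 in place of 6.04 for BIRC3 and 5.42 in place of 6.07 for IL32. Among 18 anti-apoptotic genes, 8 were at least 2-fold higher, 2 lower and 8 between (median 0.44, percentile 99.8), with BCL2A1 at 0.602 against 131 CPM and MCL1 4.66-fold higher. Among 25 pro-apoptotic genes, 7 were higher and 2 lower with a median of -0.01, whose sign changed with TMM scaling. BIK was 15.0-fold, PMAIP1 6.76-fold and the death receptor gene FAS 4.33-fold higher.

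Stress response genes differed by class. In the integrated stress and unfolded protein response list, 18 of 29 genes were at least 2-fold higher and 2 lower (median log2 fold 1.56, percentile 100). DDIT3, a transcription factor of the integrated stress response, was 19.1 against 421.6 CPM. CHAC1, which degrades glutathione, was 1.03 against 59.7 CPM, and ATF3 3.52 against 81.5 CPM. Among 26 p53 targets, 10 were higher and 3 lower, with a median of 0.36; in cells called G1 the median was -0.16. GDF15, a stress cytokine, was 23.5-fold higher, GADD45A 7.45-fold and SESN2 14.2-fold. In the MAPK output list, 8 of 19 genes were higher and 0 lower (median 0.86), with EGR1 at 2.72 against 67.5 CPM, LIF at 6.25 against 110.4 CPM and PHLDA1 at 181.4 against 970.6 CPM. Several of these differences were smaller in cells called G1, where the log2 fold was 1.44 in place of 4.20 for EGR1, 1.70 in place of 4.19 for ATF3, 2.44 in place of 4.16 for GDF15 and 2.92 in place of 4.39 for DDIT3. There it was also 2.77 in place of 3.94 for LIF, 4.0 in place of 4.9 for CHAC1 and 2.75 in place of 3.63 for SESN2. The AP-1 and dissociation stress list was divided, with 10 of 21 genes higher and 7 lower (median 0.78, percentile 100). Its heat-shock members were on the lower side. The chaperone HSPA8 (chromosome 11, 123057489 to 123063230, minus strand) was 1284 CPM (1277 to 1292) in parental and 120 CPM (117 to 122) in persister cells. HSPA1A was 26.1-fold and HSPA1B 15.4-fold lower. In cells called G1 the log2 fold was -2.46 for HSPA8, -2.28 for HSPA1A and -2.08 for HSPA1B, against -3.41, -4.08 and -3.31 in all cells. The HSPA1A and HSPA1B reads, from near-identical copies, cannot be fully separated.

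Cell cycle genes were lower in the persister library. Of 41 measured S phase genes, 24 were at least 2-fold lower and 0 higher (median log2 fold -1.18), and of 52 G2 and M phase genes, 27 were lower and 0 higher (median -1.0). Both medians lay below all matched random lists (percentile 0). TYMS, which makes thymidylate, was 242.7 against 61.9 CPM, the DNA clamp PCNA 136.8 against 33.5 CPM and the mitotic regulator CDC20 183.6 against 37.4 CPM. MKI67, a marker of cycling cells, was 309.8 CPM in parental and 142 CPM in persister cells, a log2 fold of -1.12 that was -0.42 in cells called G1. At matched depth a MKI67 UMI was found in 69.7% of parental cells (68.8 to 70.7%) and 31.4% of persister cells (30.2 to 32.6%). Unthinned these were 78.0% and 43.4%, and 42.2% of T-cell-like barcodes had one.

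Per cell, the median of G2 and M phase UMIs was 39 in parental and 11 in persister cells. At or below the parental 5th percentile of 15 UMIs lay 58.5% of persister cells (57.2 to 59.8%), while 15.1% (14.2 to 16.1%) reached the parental median. Phase scoring called 4.45% of parental cells G1, 27.0% S and 68.5% G2/M, against 55.1%, 13.5% and 31.4% of persister cells. These calls are relative scores from the S phase and the G2 and M phase lists. They do not alone show cycling, and they moved with the cell filter. Cells called G1 are picked for low scores on both lists. With 4.45% of parental cells among them, folds in G1 cells are not a clean control for phase. The S phase list summed to 3344 CPM in parental and 1631 CPM in persister cells, and the G2 and M phase list to 8758 and 4710 CPM. In the list of cell cycle inhibitors and quiescence genes, 8 of 20 were higher and 1 lower (median 0.22). CDKN1A, which encodes p21, was 39.3 against 107.5 CPM, but its log2 fold of 1.43 was 0.38 in cells called G1. BTG1 was 7.05-fold higher (log2 fold 2.8, and 2.18 in cells called G1) and HES1 4.79-fold.

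**Figure D3:**
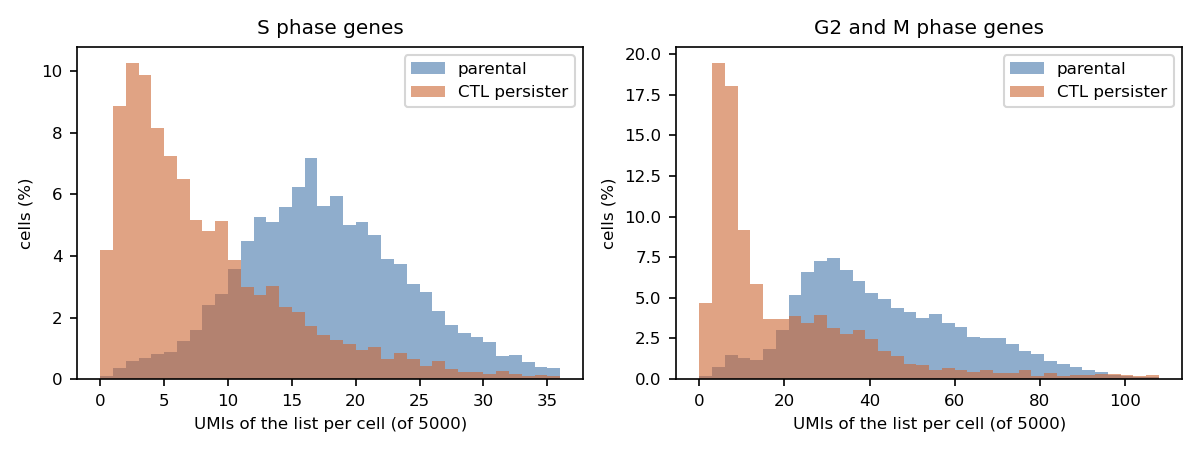
UMIs per cell from the S phase list (left) and the G2 and M phase list (right) in cells thinned to 5000 UMIs; the vertical axis is the percentage of cells of each library. The persister distribution has most cells at low values and a tail across the parental range, with 15.1% at or above the parental median of 39 UMIs for G2 and M phase genes.

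Melanocyte differentiation genes and neural crest state genes were mixed by gene. Of 13 measured melanocyte genes, from a list of 26, 10 had a log2 fold above 0. At least 2-fold higher were 4 and at least 2-fold lower 2 (median log2 fold 0.48, percentile 98.7). The higher ones included BCL2A1, also an anti-apoptotic gene, with a log2 fold of 6.36. MITF, the melanocyte master regulator, was 13.8 CPM in parental and 6.95 CPM in persister cells (log2 fold -0.89, and -1.47 in cells called G1). GPNMB was 2.95-fold lower. OCA2 was 3.67-fold higher (log2 fold 1.5, but 0.67 in cells called G1) and SOX10 1.80-fold higher. Of 22 dedifferentiated and neural crest genes, 4 were higher and 4 lower (median 0.12, percentile 94.3; -0.36 in cells called G1). AXL was 34.8 against 44.2 CPM and NGFR 5.75 against 8.40 CPM, while TFAP2B was 7.10-fold (log2 fold -2.43, and -3.84 in cells called G1) and LOXL2 3.43-fold lower. UMIs of this list had a median of 5 per thinned cell in both libraries, and 55.1% of parental cells reached the persister median. This share depended on the setting: with the stricter cell filter the medians were 5 and 6 and the share 42.8%, and without thinning, where persister cells are deeper, they were 8 and 12 and the share 27.5%. Among 24 melanoma markers, 3 were higher and 6 lower (median -0.34). MIA, a secreted melanoma protein, was 168 against 1063 CPM, whereas CAV1, a membrane scaffold protein, was 400.0 CPM (395.9 to 404.2) against 33.2 CPM (32.0 to 34.5).

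Matrix and secreted genes were mixed by gene. The mesenchymal and extracellular matrix list had 5 of 27 genes higher and 3 lower (median -0.22), but its summed CPM was 2.15-fold higher. TIMP1, a metalloproteinase inhibitor (chromosome X, 47582313 to 47586789, plus strand), was 358.9 CPM in parental and 7778 CPM in persister cells, and without it the list summed to 5289 and 4361 CPM, 0.825 times the parental value. TPM1 was 5.97-fold (log2 fold -2.57, and -1.94 in cells called G1) and COL5A1 5.74-fold lower. In the senescence-associated secretion list, 9 of 18 genes were higher and 2 lower (median 0.71), with AREG, a growth factor, at 13.3 against 273 CPM. Of 19 drug-tolerant persister genes, 7 were higher and 2 lower (median 0.39). In that list the histone demethylase KDM6B was 3.88-fold and TXNIP 3.44-fold higher, both with a log2 fold of 0.93 in cells called G1, and SOX2 was 10.4-fold lower.

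In metabolic and control lists most genes differed by less than 2-fold. Oxidative stress and ferroptosis defence genes had a median of -0.22, with 2 of 25 higher and 7 lower. Within it the cystine transporter SLC7A11 was 3.82-fold higher and DHODH 2.66-fold lower. GPX4, which detoxifies lipid peroxides, was 249.4 against 300.8 CPM. Medians were -0.36 for 28 glycolysis and hypoxia genes (4 higher, 4 lower), -0.41 for 22 cholesterol and fatty acid synthesis genes (3 higher, 3 lower) and -0.41 for 23 APOBEC and DNA damage response genes (3 higher, 4 lower). Against the negative medians of their lists, APOBEC3G, a cytidine deaminase, was 7.28-fold higher and the growth factor VEGFA 4.51-fold higher. Oxidative phosphorylation genes had medians of -0.22 (39 nuclear-encoded genes) and 0.23 (13 mitochondrially encoded genes). The median was -0.16 for 36 ribosomal protein genes, with 0 at 2-fold in either direction, and -0.35 for 26 housekeeping genes, of which ACTB was 2.45-fold and VCP 2.19-fold lower.

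The genes with the largest log2 folds included several outside these themes. LCE1E, a gene of the skin barrier, had 1 UMI in parental and 7159 UMIs in persister cells (ratio interval 1416 to 311700). At matched depth only 9.03% of persister cells had an LCE1E UMI. SPRR2D, of the same chromosomal cluster, was 5.11 against 473 CPM, but FLG, also in that region of chromosome 1, was 31.0-fold lower. The complement gene C3 was 112-fold higher, S100P 108-fold and the long non-coding RNA BANCR 288-fold. Among the lowest were MEOX2, a homeobox gene, at 69.1 against 2.96 CPM, FLG, MGP and HAPLN1, at 31.0-fold, 26.9-fold and 15.3-fold lower. PTPRF was 13.6-fold, GAL 13.1-fold, PRSS23 10.6-fold, PRRX1 8.47-fold and CPA4 8.20-fold lower. SPRY1, a feedback inhibitor of receptor signalling, was 16.1-fold lower and the replication-linked histone gene HIST1H1A 8.25-fold lower. In cells called G1 the log2 fold was 5.6 in place of 6.28 for SPRR2D, 5.18 in place of 5.81 for BANCR, -2.77 in place of -3.4 for PTPRF and -2.13 in place of -2.9 for HIST1H1A. It lay further from 0 for LCE1E (7.31 in place of 6.48), FLG (-5.05 in place of -3.92) and MGP (-4.53 in place of -3.66).

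**Figure D4:**
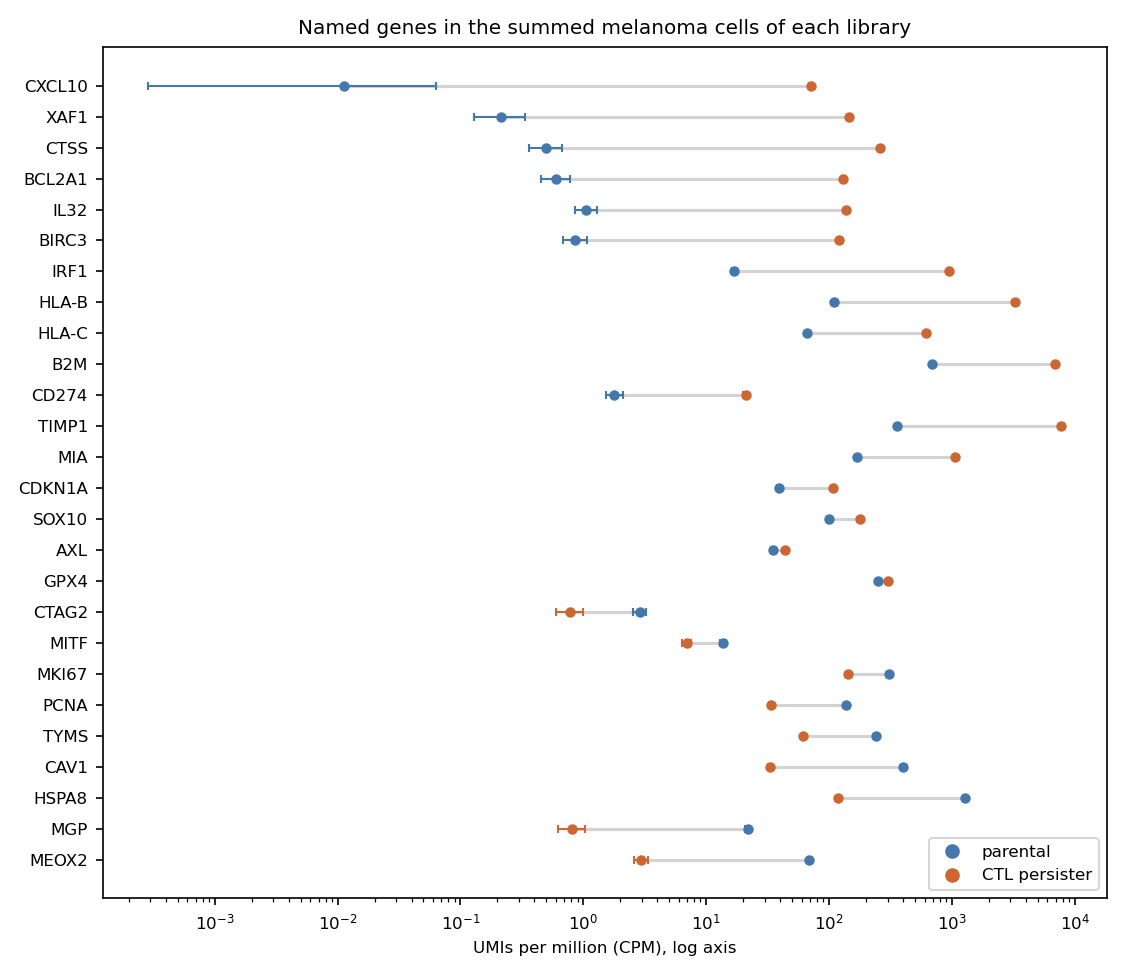
CPM of named genes in the summed melanoma cells of the parental and CTL persister libraries on a log axis; bars are 95% exact Poisson intervals, which cover counting error only. B2M goes from 684.6 to 6978 CPM and HSPA8 from 1284 to 120 CPM.

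Marker lists of other cell types, with fewer than 5 measured genes, were compared by their sums. Cytotoxic effector genes summed to 2.76 CPM in parental and 26.7 CPM in persister cells, and other blood cell markers to 275.4 and 414.2 CPM, of which CST3, also made by many tissues, was 261.6 and 384.6 CPM. Fibroblast and endothelial markers summed to 5.56 and 3.40 CPM. At matched depth the median cell had 2030 genes in the parental and 1929 genes in the persister library.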

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

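The tests in this part were set out before their results were seen, with 1 exception. The use of UMIs per cell for the question of depth was not set out beforehand. T-cell-like barcodes made up 1.99% of kept barcodes in the persister library and 0% in the parental library, with a persister share of 0.0976% under the stricter cell filter and 4.62% when barcodes with 2 or more T cell markers were counted. They stand outside the comparison of melanoma cells and above the level in the untreated control. IFNG, the gene of interferon-gamma, had 343 UMIs among the 447577 UMIs of these 135 barcodes, or 766 CPM (687 to 852). Parental clusters of 100 cells or more had 0 IFNG UMIs. Outside the T-cell-like cluster, the persister library had 19 IFNG UMIs in the unnamed low-depth cluster 10 of 377 barcodes (27.2 CPM, 16.4 to 42.6), 22 in cluster 9 and 1 each in clusters 3 and 8. These barcodes are part of the melanoma sum, and the source of their IFNG was not tested.

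The higher interferon and MHC class I genes were set against 3 technical explanations. If RNA of T cells in the melanoma sum were the cause, subtracting the T-cell-like profile would remove the difference, but the interferon-gamma list kept a median log2 fold of 3.41. For a difference in depth per cell, the list median was 3.40 in cells thinned to 5000 UMIs. That value cannot decide, because summed CPM are already scaled to the total of UMIs. The UMIs per cell can: with 5000 UMIs in each cell, the list had medians of 1 UMI in parental and 25 UMIs in persister cells. Unequal depth is thus argued against for the per-cell difference. For the list total, though not for each of its genes, a small group of cells is argued against by the 99.9% of persister cells above the parental 95th percentile. An effect of the coculture stays open and untested, because library batch and coculture coincide with 1 library per group.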

How the results depend on the processing

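No paired analysis was possible because each group has 1 library. No alternative setting reversed a list or a gene with an absolute log2 fold of at least 1 (0 of 102 named genes, 0 of 9 lists). Among smaller values, 3 named genes (CD68, CORO1A and CTAG1A) and 4 lists changed sign in at least 1 setting: AP-1 and dissociation stress with a minimum of 20 CPM (-0.33), dedifferentiated genes (-0.36) and p53 targets (-0.16) in G1 cells, and pro-apoptotic genes with TMM scaling or in G1 cells. Of 496 list medians under alternatives, 490 stayed inside the main median's interval. Of 1694 values of single genes, 994 lay outside their counting interval, which is narrow. Among 121 named genes the fold moved by over 1.5 times for 38 in G1 cells, 48 with a pseudocount of 5 CPM, 23 with 0.1 CPM and 1 with T-cell-like cells included, and for 0 in the other settings. Of 102 with an absolute log2 fold of at least 1, the value was below 1 for 8 in G1 cells, 8 with a pseudocount of 5 CPM and 2 with TMM scaling. Scrublet called no doublets, so the planned removal of called doublets gave no values. Restriction to melanoma-like clusters and removal of the highest doublet scores were chosen after seeing the data.

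Counts of genes higher and lower were 1580 and 1630 at a minimum of 1 CPM, 576 and 593 at 20 CPM, 1720 and 2538 at 1.5-fold, and 404 and 125 at 4-fold, since these settings admit more or fewer genes. The interferon-gamma median was 2.75 with a pseudocount of 5 CPM, which shrinks folds of low genes. In G1 cells the S phase median was -0.47, the G2 and M phase median -0.42, where the phase call itself selects on these genes, and the ribosomal median -0.31. The G2 and M phase median was -1.21 in thinned cells. The cause was not tested for the last 2 values.

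The T-cell-like share of persister barcodes was 0.0976% with the stricter cell filter, which cuts on genes, UMIs and mitochondrial share (at most 10%, against a median of 11.9% in the T-cell-like cluster), and 4.62% when barcodes with 2 or more T cell markers were counted; that rule gave 0.442% in the parental library, where no CTLs were added. Parental G1, S and G2/M shares were 5.29, 24.1 and 70.6% without a cell filter and 3.86, 23.8 and 72.4% with the stricter one. Persister G1 and S shares were 58.9 and 9.25% without a filter, and G1, S and G2/M shares 50.5, 10.5 and 39.0% with the stricter one. At 3000 UMIs the parental G1 and G2/M shares were 5.76 and 66.5%, and without thinning the persister ones were 52.2 and 34.9%. The cause was not tested. Median genes per cell were 1943 for persister cells with the stricter filter, for which the cause was not tested. They were 1435 and 1364 for parental and persister cells at 3000 UMIs, and 2654.5 and 3167 without thinning, where the number of UMIs per cell differs by construction. The share of parental cells reaching the persister median of dedifferentiated genes was 42.8% with the stricter filter, 56.6% at 3000 UMIs and 27.5% without thinning; for the type I interferon list it was 0.214% at 3000 UMIs and 0% without thinning.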

Other observations

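Among the tests below, the immediate-early gene test and the 3 cell cycle tests were chosen after related values had been seen, as was the split of persister cells by cell cycle UMIs.

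Interferon-gamma and MHC class I genes were high in persister cells across the cell cycle range. Of 5926 thinned persister cells, 3467 lay at or below the parental 5th percentile of G2 and M phase UMIs, and these had medians of 26 interferon-gamma list UMIs and 84 MHC class I list UMIs. The 897 cells at or above the parental median of G2 and M phase UMIs had medians of 25 and 78. In these ranges 99.9% (exact interval 99.8 to 99.99%) and 100% (99.6 to 100%) of cells lay above the parental 95th percentile of the interferon-gamma list. These are ranges of a count, not cell types.

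An unnamed cluster of 11 low-depth barcodes, 7 parental and 4 persister, was led by APOA4, APOA1, EPCAM and TTR, genes of gut or liver epithelium. It was 0.0659% of parental (0.0265 to 0.136%) and 0.0591% of persister barcodes (0.0161 to 0.151%). These genes were picked out after their values were seen.

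Heat-shock genes were lower in the persister library, with 6 of 7 measured members of the stress list at least 2-fold lower and a median log2 fold of -1.69. In cells called G1 the log2 fold of HSPA8 was -2.46 against -3.41 in all cells. This value cannot decide whether fewer G2/M cells are the whole cause, because cells called G1 still differed in cell cycle genes. There the log2 fold was -1.96 for CDC20 and -1.43 for PCNA, and the G2 and M phase list median was -0.42. The 405 parental G1 cells are also a small part of that library, and a part of the difference may come from phase. A dissociation response that was stronger in the parental library would be likely to raise immediate-early genes there too. Their median log2 fold was 1.59, with 10 of 14 at least 2-fold higher in the persister library. This cannot decide the question, because EGR1 and ATF3 among them also belong to other lists that were higher in persister cells. Such a rise in persister cells could hide a parental dissociation response, which stays open. An effect of the coculture, of its medium or of handling on a separate day also stays open and was not tested.

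Lower cell cycle genes could come from fewer cycling cells or from a lower level in every cell. The same lowering in every cell is argued against, since the 95th percentile of G2 and M phase UMIs was 0.850 times the parental one (68 against 80) while the median was 0.282 times it. Cluster 9 (2375 thinned cells) had a median of 33 UMIs with 5.64% of cells at or below the parental 5th percentile, and cluster 8 (2870 cells) a median of 6 with 96.1%, though these genes helped to form the clusters. Whether fewer cycling cells are the whole cause stays open, because the 15.1% of persister cells at or above the parental median lay between the bounds of 25% and 10% set for that outcome. Unnamed barcodes of low depth hold 0.879% of summed persister UMIs, too small a share to lower a summed level 2-fold. Their low depth made a large share unlikely from the start, so this adds little as a test.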
